A study of Mus musculus with 8 samples.

How the data were processed

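Left ventricle tissue of C57BL/6 mice was profiled on 8 one-colour expression arrays, 2 for each of 4 reproductive states. Per the labels' protocols, the left ventricle was dissected and cut into pieces, RNA of 1 piece was isolated with Trizol and silica columns, and 100 ng of total RNA was converted to fragmented, biotin-labelled single-stranded cDNA. The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, equalises the distribution of the arrays and summarises the probes of a probe set. The versions and settings, the array library file and the genome build are not given in the sources used here. Because the arrays were equalised before deposit, a change in total RNA per cell cannot be seen, and small changes shared by most genes are removed.

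The table held 34365 probe sets on 8 arrays, with values from 1.37 to 13.32 and array medians from 5.14 to 5.28. An annotation table of the platform listed 25335 of the probe sets: 23521 with 1 gene symbol and 1814 with several, while the other 9030 were unnamed here. Entrez identifiers of 23328 of the single-symbol probe sets matched a mouse reference gene table (GRCm38.p6, used for names and for which genes contain each other), and 0 symbols changed. Of several probe sets of 1 gene, the one with the highest mean over the 8 arrays was used, which gave 22180 genes. A gene was tested if the mean of at least 1 group reached the median of all values, 5.19, which left 13872 genes. Beside each named gene with another probe set, the other probe set was read as well.

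Groups and replicate numbers came from the sample titles and stage labels. A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, so that the 4 groups shared 1 estimate of the spread, with 4 residual and 3.68 prior degrees of freedom from eBayes. The 3 states were compared with diestrus, as the series design names it the reference, and 2 further contrasts set day 19 against day 12 and post-partum day 1.5 against day 19. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A moderated F test covered the 3 contrasts with diestrus together. The labels name separate samples but say nothing of which animals they came from, so p-values measure the spread between these samples only. The number of arrays limits the precision: the typical moderated standard error of a log2 fold change was 0.17.

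Before the data were examined, 36 gene lists were fixed, of pathways, matrix classes and cell type markers: collagens, basement membrane, matrix glycoproteins, proteoglycans, matrix enzymes, integrins, hypertrophy markers, sarcomere, calcium handling, ion channels, fatty acid use, glucose use, oxidative phosphorylation, cholesterol synthesis, cell cycle, ribosomal proteins, ER stress, heat shock, vascular growth, hormone response, glucocorticoid targets, circadian clock, immediate-early genes, interferon response, macrophage, neutrophil, lymphocyte, MHC class II, erythrocyte, fibroblast, endothelial, mural, adipocyte, atrial, nerve and mesothelium. Some genes stand in more than 1 list. The 34 lists with at least 5 members among the genes tested were tested with camera at its preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison; 2 lists were too small. The test was repeated with the correlation estimated per list and with fry. Members were also counted as passing over all genes tested and adjusted over the list alone.

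The rule for named genes was fixed at the same time. It takes, for each comparison with diestrus, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, filled from genes of unadjusted p under 0.01 where fewer passed, leaving out predicted genes and numbered small RNA genes. For the successive stages it takes 5 in each direction. It adds up to 4 members of each list with the smallest p, and Nppa, Nppb, Myh7, Acta1, Col1a1, Col3a1 and Hba-a1, of which the last was not among the genes measured here. List members are printed for the lists past the threshold against diestrus only, a narrowing made after the values were seen.

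The model and the list test were first tested on simulated data: 8 arrays with the real gene means, variances drawn from the fitted prior, 200 changed genes in the day 19 group and a shift of 0.3 in the cell cycle list, in 20 runs of 13872 genes. Of the genes changed 2-fold, 51.4% were recovered in that simulated comparison, and of those changed 4-fold, 94%, with a mean of 7.1 false calls per run. The shifted list was called in 20 of the 20 runs with the preset correlation and in 4 with an estimated correlation. The simulation gave all arrays the same spread and drew genes independently.

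Alternatives covered array weights, a trended and robust variance, no filter and a stricter filter at the 75th percentile (6.86), repeated quantile normalization, median centring, fits of the compared groups only, every probe set on its own, other thresholds, the replicate number as a block, and leaving out each array in turn, where a lone array is assumed to vary like the other groups. After seeing the data, 2 more were added: leaving out day 19 replicate 2 and post-partum replicate 2 together, and the mean of the atrial markers without Nppa as a covariate. Overlaps between comparisons with the shared diestrus arrays were set against 100 simulations of unchanged groups.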

Results

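Gene expression in the cardiac left ventricle was measured in mice in 4 states, with 2 arrays per state. The states were diestrus, a phase of the estrous cycle, day 12 of pregnancy, day 19 of pregnancy and day 1.5 after birth. The protocol text gives the late group as 18/19 days. Diestrus was represented by replicates 2 and 3, day 12 by replicates 2 and 3, day 19 by replicates 1 and 2 and post-partum by replicates 2 and 4. Values are log2 RMA intensities. Over all probe sets, the correlation between arrays was 0.980 to 0.992 among 7 of the arrays and 0.969 to 0.977 between day 19 replicate 2 and the others. The standard deviation of the difference between the 2 arrays of a group was 0.264 in diestrus, 0.239 at day 12, 0.555 at day 19 and 0.328 post-partum. Between the 2 day 19 arrays, 652 genes differed by more than 1 log2 unit, against 90, 68 and 145 in diestrus, at day 12 and post-partum.

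**Figure D1:**
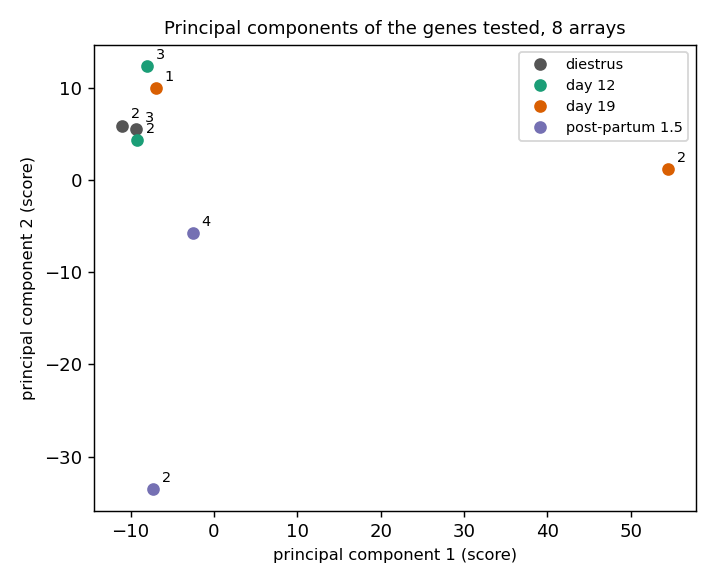
Scores of the 8 arrays on the first and second principal components of the genes tested, coloured by group and numbered by replicate. Component 1 (47.1% of the variance) sets day 19 replicate 2 apart at 54.5, and component 2 (20.6%) sets post-partum replicate 2 apart at -33.6.

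The comparison of day 12 with diestrus asked how the left ventricle differed at mid-pregnancy. Genes of fatty acid use rose as a list: all 31 measured members were higher at day 12, with a median log2 change of 0.21 (camera, adjusted p = 7.35e-11; adjusted p = 0.979 with an estimated correlation). Its leading members were Angptl4, an inhibitor of lipoprotein lipase (0.86 ± 0.18 log2, SE, n = 2 per group), and Pdk4, a kinase that restrains pyruvate dehydrogenase (0.90 ± 0.20), followed by Plin5, a lipid droplet protein (0.58), and the mitochondrial carrier Ucp3 (0.59). Proteoglycan genes fell as a list, with 10 of 10 members lower and a median of -0.32 (adjusted p = 4.67e-06; adjusted p = 0.979 with an estimated correlation), among them Omd at -0.54, Ogn at -0.33, Bgn at -0.29 and Vcan at -0.21. With each array left out in turn Omd ranged from -0.78 to -0.30, and Ucp3 from 0.36 to 0.82.

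Smaller shifts at day 12 passed the list test in 4 further groups. Fibroblast markers fell by a median of 0.15 on the log2 scale with 14 of 15 members lower (adjusted p = 0.00206), led by Pdgfra (-0.26), Mfap5 (-0.56), Islr (-0.51) and Tcf21 (-0.41). Matrix glycoproteins fell with 23 of 30 members lower and a median of -0.15 (adjusted p = 0.00324), led by the growth factor-binding protein Ccn2 (-1.00), Fbln1 (-0.37) and Tnxb (-0.24). Ribosomal protein genes fell with 23 of 32 lower and a median of -0.069 (adjusted p = 0.0104), including Rps16 (-0.47), Rps27 (-0.78), Rpl32 (-0.40) and Rpl19 (-0.23). Glucocorticoid targets rose with 12 of 16 higher and a median of 0.19 (adjusted p = 0.0104), including Mt2 (0.36), Fkbp5 (0.39), Zbtb16 (0.60) and Pik3r1 (0.25). The adjusted p with an estimated correlation was 0.979 for each of these 4 lists. Leaving out each array in turn, Mfap5 ranged from -0.79 to -0.33, Tnxb from -0.40 to -0.087, Rps27 from -1.12 to -0.44, Rpl19 from -0.33 to -0.13, Fkbp5 from 0.25 to 0.54, Zbtb16 from 0.39 to 0.81 and Pik3r1 from 0.16 to 0.33. The other 28 lists did not pass (adjusted p = 0.0666 to 0.964), the nearest being the interferon response, with 17 of 17 members higher and a median of 0.39.

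Single genes at day 12 were ranked among those of unadjusted p under 0.01, without predicted and numbered small RNA genes. The largest higher values were those of Slc4a1, the anion exchanger of red cells, at 1.27 ± 0.24 log2 or 2.40-fold, Lgals4 at 1.19, the carbonic anhydrase Car2 at 1.14 ± 0.16, Btnl9 at 1.04 and the retinol-binding protein Rbp7 at 0.92. Olfr1396 (0.90), Tent5c (0.89) and Olfr1348 (0.74) followed. Of the other red cell genes tested, Bpgm gave 0.47, Ank1 -0.42 and Fech -0.020 at day 12, and Epb42, which was measured but below the filter, stood at 4.17 and 4.24 on the diestrus arrays and at 4.85 and 4.91 at day 12. Slc4a1 stood at 6.07 and 6.07 on the diestrus arrays and at 7.08 and 7.59 at day 12. Within the same limits the lowest values were those of Ep400 (-1.28), Ccn2 (-1.00), Ppan (-1.00), the growth factor Nrg1 (-0.85), Etv5 (-0.78), the insulin-degrading enzyme Ide (-0.76), Rad51ap1 (-0.65), Scgb1c1 (-0.63), Olfr38 (-0.57) and Camk2n1 (-0.51). The other probe sets of Ep400, Ppan, Ccn2 and Etv5 gave -0.038, -0.049, 0.18 and 0.090. None of these genes passed the threshold.

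In that comparison 0 of 13872 genes passed in limma, with a smallest adjusted p of 0.329. An unadjusted p under 0.05 was found for 321 genes, where chance gives 694. The spread was shared by the 4 groups and was widest in the day 19 pair (standard deviation of the difference 0.555, against 0.264 in diestrus and 0.239 at day 12). The standard errors and p-values here are therefore not those of day 12 and diestrus alone. With only these groups fitted no gene passed either. Whether the shared spread accounts for the low count was not tested. Of the fatty acid list, Angptl4 and Pdk4 passed when adjusted over the list alone, and 0 members of the other called lists did. The calls of fatty acid use and proteoglycans held with each of the 8 arrays left out, the proteoglycan mean of -0.32 going to -0.18 without diestrus replicate 3, while those of matrix glycoproteins, ribosomal proteins and fibroblast markers ended without diestrus replicate 3 or without day 12 replicate 2 (highest adjusted p = 0.520, 0.990 and 0.260). Without diestrus replicate 3 the mean of the ribosomal list was 0.012. Over the arrays left out the mean of matrix glycoproteins ranged from -0.31 to -0.054, that of fibroblast markers from -0.30 to -0.15 and that of glucocorticoid targets from 0.11 to 0.18. The call of glucocorticoid targets ended without diestrus replicate 2 or day 12 replicate 3 (highest adjusted p = 0.360).

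The comparison of day 19 with diestrus addressed late pregnancy. Immediate-early genes, which respond within minutes to a stimulus and many of which encode transcription factors, rose as a list, with 17 of 20 members higher and a median of 0.55 (adjusted p = 3.93e-07; adjusted p = 0.543 with an estimated correlation), among them Atf3 (1.52 ± 0.33), Btg2 (0.96), Egr2 (0.74) and Fosb (0.59). Genes of the endoplasmic reticulum stress response rose with 19 of 21 members higher and a median of 0.29 (adjusted p = 3.27e-06; adjusted p = 0.543 with an estimated correlation), among them the chaperone Hspa5 (0.39), Hyou1 (0.40), Creld2 (0.58) and Sdf2l1 (0.82). Both lists were higher than diestrus on each day 19 array: immediate-early genes averaged 0.26 and 0.70 above the diestrus mean on replicates 1 and 2, and the stress list 0.14 and 0.43. Without replicate 2 Atf3 gave 0.96, Btg2 0.57, Egr2 0.43, Hyou1 0.24 and Sdf2l1 0.40, and without diestrus replicate 3 Sdf2l1 gave 0.54.

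Hypertrophy markers rose as a list at day 19, with 10 of 15 members higher and a median of 0.60 (adjusted p = 8.33e-04; adjusted p = 0.543 with an estimated correlation). Myh7, the slow beta myosin heavy chain, stood at 6.98 and 6.41 in diestrus and at 8.99 and 9.69 at day 19, a difference of 2.65 ± 0.35 log2 or 6.28-fold (adjusted p = 0.503). Myc (0.60), Rcan1 (0.84), a target of calcineurin, and Ankrd2 (0.81) followed, and the natriuretic peptide genes Nppb and Nppa gave 0.89 and 0.74. The skeletal actin gene Acta1 gave 0.72, with 10.21 on replicate 1 and 8.78 on replicate 2. Without replicate 1 Acta1 gave 0.0047 and Nppa 0.29, and with each array left out in turn Nppa ranged from 0.29 to 1.18, Nppb from 0.42 to 1.36, Rcan1 from 0.49 to 1.19 and Ankrd2 from 0.43 to 1.20. Col1a1 and Col3a1 gave 0.030 and 0.13, and -0.22 and -0.15 without replicate 1. The atrial list also rose, with 8 of 10 higher and a median of 0.64 (adjusted p = 0.0330; adjusted p = 0.543 with an estimated correlation); it holds Nppa, and its marker Myl7 was 11.76 on replicate 1 and 4.56 on replicate 2. The mesothelium list rose with 9 of 10 higher and a median of 0.43 (adjusted p = 0.00340; adjusted p = 0.543 with an estimated correlation), including Krt8 (0.36), Cldn15 (0.62), Msln (0.81) and Upk1b (0.98), and averaged 0.97 and -0.10 on the 2 arrays. Without replicate 1 the atrial mean turned to -0.38 and the mesothelium mean to -0.10, and the calls of hypertrophy markers and mesothelium ended (adjusted p = 0.0941 and 0.880), the hypertrophy mean going from 0.46 to 0.36. Cldn15, Msln and Upk1b gave 0.21, 0.018 and -0.21 without replicate 1. Of the atrial list, Bmp10 ranged from 0.51 to 3.46 over the arrays left out, Gja5 from 0.22 to 0.43 and Kcnj3 from -0.59 to -0.31. Without diestrus replicate 2 the atrial and mesothelium calls ended as well (adjusted p = 0.175 and 0.129).

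Of the immune lists, 3 rose at day 19, with high values on replicate 2 alone. Interferon response genes had 16 of 17 members higher and a median of 1.20 (adjusted p = 5.73e-07), with Isg15 at 1.20, Bst2 at 1.47, Rsad2 at 1.15 and Usp18 at 1.48. Macrophage markers had 17 of 18 higher and a median of 0.68 (adjusted p = 3.27e-06), with Fcgr1 at 1.36, C1qa at 0.79, C1qc at 0.79 and Lyz2 at 0.68, and MHC class II genes had 6 of 6 higher and a median of 1.07 (adjusted p = 0.0211), with Ciita at 1.06, H2-DMa at 1.31, H2-Eb1 at 1.08 and H2-Ab1 at 1.09. When the correlation was estimated, the adjusted p was 0.543 for each of the 3. Against the diestrus mean, the interferon list averaged 0.024 on replicate 1 and 2.42 on replicate 2, the macrophage list 0.096 and 1.10, and the MHC class II list -0.29 and 2.07. Without replicate 2 the first and second of these calls ended (adjusted p = 0.735 and 0.367), and the MHC class II list passed as lower, with a mean of -0.29 (adjusted p = 0.00515). In that setting Isg15, Bst2, Rsad2 and Usp18 gave 0.52, 0.30, 0.25 and 0.26, Fcgr1, C1qa, C1qc and Lyz2 0.21, 0.11, 0.16 and 0.23, and Ciita, H2-DMa, H2-Eb1 and H2-Ab1 -0.017, -0.31, -0.31 and -0.42. Without diestrus replicate 3 the MHC class II call ended (adjusted p = 0.0637).

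Cell cycle genes rose at day 19 with 28 of 35 higher and a median of 0.26 (adjusted p = 2.50e-04), with Top2a at 0.91, Ccna2 at 0.54 and Ube2c at 0.47 but Cenpf at -0.94. Glucocorticoid targets rose with 9 of 16 higher and a median of 0.072 (adjusted p = 0.0294), carried by Cdkn1a (1.51), Lcn2 (1.41) and the metallothioneins Mt2 (0.95) and Mt1 (0.60); with each array left out in turn Lcn2 ranged from 0.63 to 2.20, Top2a from 0.55 to 1.27 and Ube2c from 0.23 to 0.71. Fatty acid use rose with 18 of 31 higher and a median of 0.056 (adjusted p = 0.0397), with Angptl4 at 1.12, Pdk4 at 0.77, Decr1 at 0.29 and Eci1 at 0.26. The adjusted p with an estimated correlation was 0.543 for the first and second of these lists and 0.645 for fatty acid use. On day 19 replicates 1 and 2, against the diestrus mean, cell cycle genes averaged 0.043 and 0.37, glucocorticoid targets 0.19 and 0.27 and fatty acid use 0.21 and 0.0011, and Eci1 gave 0.18 without replicate 1. The cell cycle call ended without day 19 replicate 2 or diestrus replicate 2 (highest adjusted p = 0.566), that of glucocorticoid targets without day 19 replicate 1 or diestrus replicate 2 (0.154), and that of fatty acid use without day 19 replicate 1 or diestrus replicate 3 (0.959).

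The lists that fell at day 19 were oxidative phosphorylation, with 50 of 50 members lower and a median of -0.15 (adjusted p = 3.45e-04), ion channels with 18 of 19 lower (-0.25, adjusted p = 3.76e-04), proteoglycans with 9 of 10 lower (-0.36, adjusted p = 0.00192) and fibroblast markers with 13 of 15 lower (-0.25, adjusted p = 0.00734). Mural cell markers fell with 11 of 13 lower (-0.28, adjusted p = 0.0109), calcium handling genes with 15 of 16 lower (-0.15, adjusted p = 0.0135) and vascular growth genes with 21 of 25 lower (-0.20, adjusted p = 0.0450). With an estimated correlation the adjusted p was 0.566 for oxidative phosphorylation and 0.543 for each of the other 6. Against the diestrus mean, oxidative phosphorylation averaged 0.0055 and -0.32 on day 19 replicates 1 and 2, ion channels -0.11 and -0.47, proteoglycans -0.15 and -0.70 and fibroblast markers -0.012 and -0.58. Mural markers averaged -0.12 and -0.38, calcium handling -0.022 and -0.36 and vascular growth -0.098 and -0.22. The lower of each pair of means was that of replicate 2, the array on which the immune lists were high. Members with the smallest p were the potassium channel genes Kcnd2 (-0.70), Kcnh2 (-0.47), Kcnj3 (-0.45) and Kcnd3 (-0.54), the proteoglycans Omd (-1.14), Ogn (-0.54), Aspn (-0.91) and Prelp (-0.44), and Aplnr, the apelin receptor (-1.44, and -0.72 without replicate 2). In the calcium list Hrc gave -0.58, Trdn -0.37 and Cacna2d1 -0.37, among mural markers Myh11 gave -0.38, Notch3 -0.36 and Cnn1 -0.63, and among fibroblast markers Scara5 gave -0.56 and Lum -0.69. In oxidative phosphorylation Ndufa1 gave -0.48, Cycs -0.23 and Cox5b -0.27. Other members picked by p are given as ranges over the arrays left out. Among vascular growth genes Fgf1 ranged from -0.32 to -0.28 and Tie1 from -0.60 to -0.13. Angpt2 went against its list, from 0.18 to 1.45. Islr ranged from -1.12 to -0.34, Tcf21 from -1.07 to -0.010 and Rgs5 from -0.58 to -0.19. S100a1 ranged from -0.48 to -0.11 and Cox7a1 from -0.31 to -0.15. Without replicate 2 Kcnd3 gave -0.18, Omd -0.68, Aspn -0.40, Prelp -0.15, Hrc -0.34, Cacna2d1 -0.078, Cnn1 -0.24, Lum -0.20, Ndufa1 -0.064 and Cox5b -0.081, and without diestrus replicate 3 Myh11 gave -0.21 and Cnn1 -0.25. Without day 19 replicate 2 the calls of oxidative phosphorylation, ion channels, calcium handling and fibroblast markers ended (adjusted p = 0.735, 0.0571, 0.566 and 0.682). Without day 19 replicate 1 those of mural markers and vascular growth ended (adjusted p = 0.0717 and 0.247). Leaving out diestrus replicate 2 ended those of calcium handling and vascular growth (adjusted p = 0.0563 and 0.0935). Leaving out diestrus replicate 3 ended those of proteoglycans, fibroblast markers, mural markers and vascular growth (adjusted p = 0.0640, 0.0854, 0.0854 and 0.0986). The 16 lists not called at day 19 had an adjusted p of 0.0609 to 0.693.

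At day 19 single genes were ranked among those of unadjusted p under 0.01, without predicted and numbered small RNA genes. The highest difference was that of the B cell chemokine Cxcl13, 3.26 ± 0.65 log2 or 9.58-fold, with 7.96 and 10.44 on the day 19 arrays against 5.84 and 6.05 in diestrus. Myh7 came next, then the monocyte chemokine Ccl2 (2.59), Apol9b (2.36), the acute-phase inhibitor Serpina3n (2.14 ± 0.34), complement C4b (2.02), Plek (1.71), Nmrk2 (1.70), Itgax (1.60) and Atf3. Within the same limits the lowest were Abca6 (-1.36), Klra9 (-1.31), Slc9a2 (-1.20), Smoc2 (-1.17), Omd, Nrep (-1.11), Cdh19 (-1.10), Olfr713 (-1.04), Atcayos (-1.03) and Necab1 (-1.02). Without replicate 2 Cxcl13 gave 2.02, Ccl2 1.37, Apol9b 1.14, C4b 1.11, Itgax 0.90 and Atf3 0.96, and Abca6 -0.75, Smoc2 -0.64, Omd -0.68, Nrep -0.59, Cdh19 -0.68 and Atcayos -0.58. Without replicate 1 Apol9b gave 3.58 and Olfr713 -0.68. None of these genes passed the threshold.

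At day 19, 0 genes passed in limma, with a smallest adjusted p of 0.181. An unadjusted p under 0.05 was found for 1011 genes (694 by chance), of which 235 were higher and 159 lower by at least 1.5-fold. The day 19 arrays differed more (standard deviation 0.555) than the other pairs (0.239 to 0.328), while the model shared 1 spread. In every comparison that holds day 19, standard errors and p-values may therefore be too small. The excess over 694 is by itself no evidence of change. Adjusted over the list alone, 5 immediate-early genes (Atf3, Btg2, Egr2, Fos and Fosb), 5 hypertrophy markers (Ankrd2, Myc, Myh7, Nppb and Rcan1), 3 glucocorticoid targets (Cdkn1a, Mt1 and Mt2), 2 proteoglycans (Ogn and Omd) and Angptl4 passed, and of lists not called the matrix enzymes Mmp19 and Timp1 and the hormone response gene Gper1. The count was 1233 without day 19 replicate 1 and 2 without day 19 replicate 2 (Bmp10 and Cxcl13), and Cxcl13 was the 1 gene in both.

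**Figure D2:**
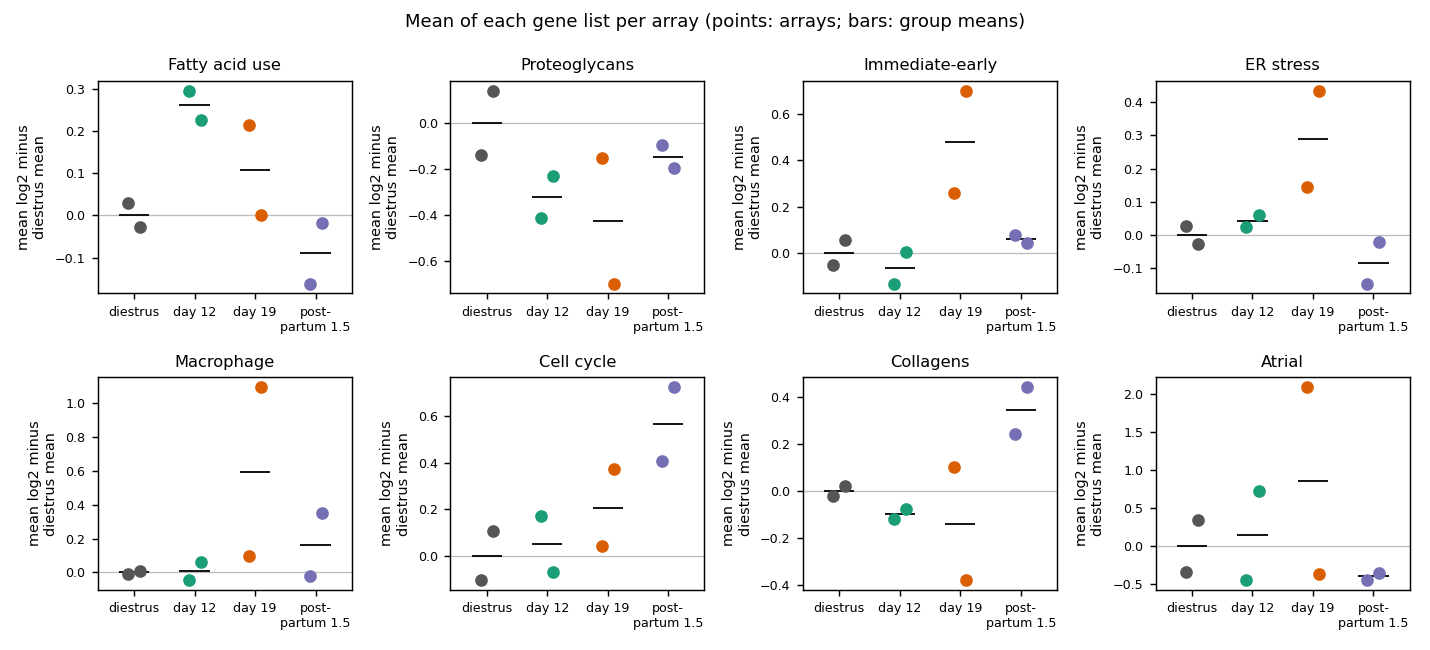
Mean log2 value of 8 gene lists on each array minus the diestrus mean, by group; points are the 2 arrays and bars the group means. Fatty acid use is highest at day 12 (0.30 and 0.23), macrophage markers on day 19 replicate 2 (1.10), atrial markers on day 19 replicate 1 (2.10) and cell cycle genes post-partum (0.41 and 0.72).

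The comparison of post-partum day 1.5 with diestrus addressed the days just after birth. Cell cycle genes rose as a list, with 34 of 35 members higher and a median of 0.49 (adjusted p = 1.15e-19; adjusted p = 0.906 with an estimated correlation). Cyclin A2, Ccna2, was higher by 1.21 ± 0.19, Ube2c by 1.19 ± 0.18, Cdk1 by 1.14 ± 0.22 and the replication helicase gene Mcm3 by 0.86. Collagen genes rose with 13 of 14 higher and a median of 0.31 (adjusted p = 1.80e-04; adjusted p = 0.906 with an estimated correlation), with Col8a1 at 1.39 ± 0.37, Col1a1 at 0.58, Col6a3 at 0.54, Col5a1 at 0.48 and Col3a1 at 0.41. Hypertrophy markers rose with 11 of 15 higher and a median of 0.16 (adjusted p = 0.0404; adjusted p = 0.906 with an estimated correlation), with Acta1 at 1.37 ± 0.43, Rcan1 at 0.73, Nppb at 0.56 and Tgfb1 at 0.43, while Myh7 and Nppa gave 0.53 and 0.14. Nppa gave -0.31 without diestrus replicate 3, -0.27 without post-partum replicate 4 and -0.52 with the replicate number as a block, and with each array left out in turn Nppb ranged from 0.090 to 1.03, Myh7 from 0.19 to 0.87 and Rcan1 from 0.38 to 1.08.

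Post-partum, single genes were ranked among those of unadjusted p under 0.01, without predicted and numbered small RNA genes. The largest higher value was that of Tnc, the matrix protein tenascin C, at 7.13 and 7.75 against 5.56 and 5.29 in diestrus, a difference of 2.01 ± 0.24 or 4.04-fold (adjusted p = 0.445). The linker histone H1f5 (1.80), the metalloproteinase inhibitor Timp1 (1.56 ± 0.26), the retinoic acid enzyme Aldh1a2 (1.18), Top2a (1.17) and Dtl (1.02) followed. Within the same limits the lowest were H2-Q10 (-1.40), Omd (-1.31), the enkephalin precursor Penk (-1.27), Tc2n (-1.16), Prxl2a (-1.03), Dhdh (-1.02), Nrxn2 (-1.01), Klra9 (-1.01), Ide (-1.00 ± 0.13) and Ugt3a1 (-0.99). Without post-partum replicate 2 H2-Q10 gave -0.74, Dhdh -0.53 and Klra9 -0.56. The other probe sets of H2-Q10, Nrxn2 and Col5a1 gave 0.25, -0.0096 and -0.29. None of these genes passed the threshold.

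Post-partum, 0 genes passed in limma, with a smallest adjusted p of 0.445; 918 had an unadjusted p under 0.05 (694 by chance), of which 99 were higher and 146 lower by at least 1.5-fold. Adjusted over the list alone, 15 cell cycle genes passed (Anln, Ccna2, Ccnb2, Ccnd1, Cdc20, Cdk1, Mcm2 to Mcm7, Mki67, Top2a and Ube2c) and 2 collagens (Col5a1 and Col8a1), and of lists not called Tnc, Omd, Vcan, Timp1, Mt2 and Cspg4. The cell cycle call held with each array left out, the collagen call ended without post-partum replicate 4 (mean 0.25 against 0.35, adjusted p = 0.280), and that of hypertrophy markers ended without post-partum replicate 4 or diestrus replicate 3 (highest adjusted p = 0.282), while its mean of 0.30 ranged from 0.27 to 0.33 over the arrays left out. The other 31 lists did not pass (adjusted p = 0.0630 to 0.903). A moderated F test over the 3 states gave 0 genes, with a smallest adjusted p of 0.263.

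**Figure D3:**
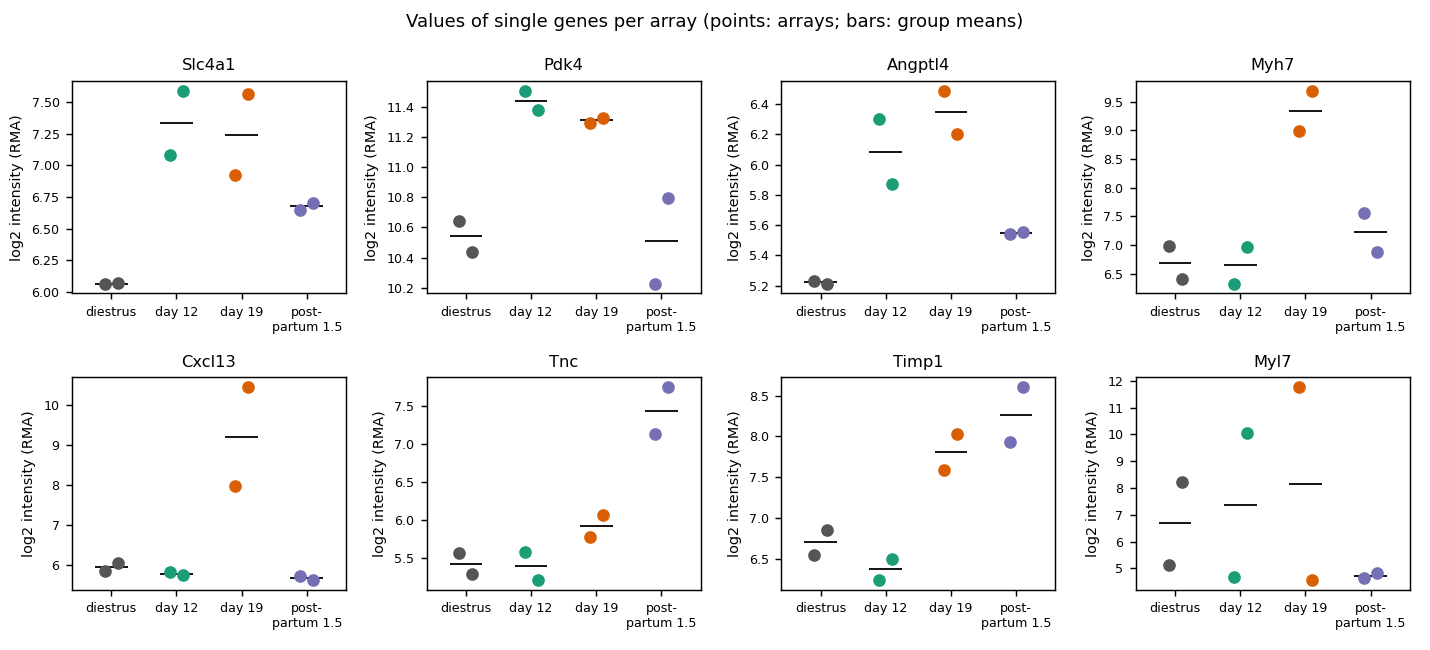
Log2 RMA intensity of 8 genes on each array, by group; points are the 2 arrays and bars the group means, and each panel has its own axis. Myh7 lies at 8.99 and 9.69 at day 19, Tnc at 7.13 and 7.75 post-partum, and Myl7, an atrial marker, between 4.56 and 11.76 within the day 19 pair.

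Day 19 was set against day 12 to compare late with mid-pregnancy without the diestrus arrays. Of 34 lists 19 passed, 12 up and 7 down. Immediate-early genes rose with 20 of 20 higher and a median of 0.56 (adjusted p = 4.72e-10; adjusted p = 0.449 with an estimated correlation), ER stress genes with 20 of 21 higher (0.22, adjusted p = 1.51e-05; adjusted p = 0.524 with an estimated correlation), and ion channels fell with 18 of 19 lower (-0.31, adjusted p = 1.48e-04; adjusted p = 0.524 with an estimated correlation). These 3 calls held with each array left out, but without day 19 replicate 2 their means of 0.55, 0.25 and -0.30 went to 0.33, 0.10 and -0.12. The other 16 did not hold: without day 19 replicate 2, 6 ended and 4 turned in direction, without day 19 replicate 1, 5 and 1, and without day 12 replicate 2, 7 ended. The 15 lists not called had an adjusted p of 0.0578 to 0.749. Single genes were ranked among those of unadjusted p under 0.01, without predicted and numbered small RNA genes. Of these Cxcl13 (3.42), Ccl2 (2.94), Myh7 (2.70 ± 0.35), Serpina3n (1.61) and Ccl6 (1.61) had the largest higher values at day 19, and Mrgprh (-1.16), Lgals4 (-1.07), Slc9a2 (-0.99), Ucp3 (-0.91) and Ablim3 (-0.88) the lowest. Leaving out day 19 replicate 2, Cxcl13 gave 2.18, Ccl2 1.72, Ccl6 1.02 and Ablim3 -0.47. In limma 0 genes passed (smallest adjusted p = 0.675), and 898 had an unadjusted p under 0.05. Without day 19 replicate 1 there were 1312 and without replicate 2 there were 2; without replicate 2 the interferon and MHC class II lists passed as lower, with means of -0.36 and -0.24 (adjusted p = 8.13e-08 and 0.0365).

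Post-partum was set against day 19 to follow the passage through birth. Of 34 lists 16 passed, 8 up and 8 down. ER stress genes fell with 19 of 21 lower and a median of -0.34 (adjusted p = 1.97e-08), while collagens rose with 12 of 14 higher (0.38, adjusted p = 7.87e-05) and basement membrane genes rose with 15 of 18 higher (0.28, adjusted p = 5.76e-04). The adjusted p with an estimated correlation was 0.572 for each of these 3. They held with each array left out, but without day 19 replicate 2 the means of ER stress and collagens went from -0.37 and 0.48 to -0.23 and 0.24. The other 13 did not hold: without day 19 replicate 2, 7 ended and 2 turned, without day 19 replicate 1, 5 ended, and without post-partum replicate 4, 4. The 18 lists not called had an adjusted p of 0.0514 to 0.909. Single genes were again ranked among those of unadjusted p under 0.01, without predicted and numbered small RNA genes. Of these Col8a1 (2.00 ± 0.37), H1f5 (1.58), Tnc (1.52 ± 0.24), Col15a1 (1.21) and H2bc18 (1.11) had the largest higher values post-partum, and Cxcl13 (-3.53), Myh7 (-2.12 ± 0.35), C4b (-1.92), Plek (-1.88) and Cd226 (-1.74) the lowest. Without day 19 replicate 2 Cxcl13 gave -2.29, C4b -1.01, Col15a1 0.59 and Col8a1 1.35, without day 19 replicate 1 Col15a1 gave 1.83, and without post-partum replicate 2 H2bc18 gave 0.64. In limma 0 genes passed (smallest adjusted p = 0.0667), and 1145 had an unadjusted p under 0.05. Without day 19 replicate 1 there were 872, without replicate 2 there were 2, and without post-partum replicate 4 there were 4.

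The lists that passed in none of the 5 comparisons are given as median log2 changes against diestrus at day 12, day 19 and post-partum. They were 0.026, -0.076 and 0.040 for the sarcomere, 0.056, 0.031 and -0.095 for integrins, 0.070, -0.018 and 0.056 for glucose use, and 0.0012, -0.025 and -0.066 for cholesterol synthesis. Heat shock genes gave 0.057, 0.091 and 0.15, hormone response genes -0.0058, -0.19 and -0.096, adipocyte markers 0.028, 0.28 and -0.16, and nerve markers -0.030, 0.011 and -0.10. Of lists called between successive stages alone, basement membrane gave 0.040, -0.11 and 0.11, matrix enzymes gave -0.046, 0.090 and 0.077, the circadian clock -0.016, -0.39 and 0.12, endothelial markers 0.11, -0.13 and -0.013, and lymphocyte markers -0.095, 0.42 and -0.28. The median, the mean or the tested direction of a list differed in sign in 15 cases, 0 of them called. These were integrins, cholesterol synthesis, vascular growth, circadian clock, macrophage, MHC class II and adipocyte at day 12, glucose use at day 19, endothelial post-partum, collagens and glucocorticoid targets from day 12 to day 19, and matrix enzymes, glucose use, cholesterol synthesis and ribosomal proteins from day 19 to post-partum. Of the lists too small to test, the 2 neutrophil genes tested, Csf3r and Cxcr2, gave 1.03 and 0.51 at day 19, and the 4 red cell genes tested, Slc4a1, Bpgm, Ank1 and Fech, gave 1.17, 0.16, -0.13 and -0.31 at day 19 and 0.61, 0.15, 0.30 and -0.29 post-partum. Csf3r and Cxcr2 gave 0.17 and 0.099 at day 12 and 0.15 and 0.069 post-partum.

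Of genes with an unadjusted p under 0.05 and at least 1.5-fold, 35 were shared in direction by day 12 and day 19, 11 by day 12 and post-partum and 42 by day 19 and post-partum, and 0 passed the adjusted threshold. Independent sets of those sizes would share 0.847 higher and 0.562 lower genes in the first pair, 0.357 and 0.516 in the second and 1.68 and 1.67 in the third, while 100 simulations of unchanged groups against the shared diestrus arrays gave a median of 38. Across genes, which are not independent replicates, the fold changes correlated at 0.366, 0.293 and 0.354 against a simulated 0.500 to 0.501, with covariances of 0.0232, 0.0145 and 0.0303 against a simulated 0.0246, 0.0247 and 0.0246. The 2 diestrus arrays were too few to be split between the comparisons. The simulations gave all 4 groups the same spread. In the data the standard deviation of the difference between 2 arrays was 0.264 in diestrus and 0.555 at day 19. The simulated sharing may therefore be too high, and it does not decide whether the shared arrays alone account for the overlaps.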

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

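All tests of explanations in this part were chosen after the result was seen. Lists whose effects differed between successive stages by the tested contrast are given as mean log2 differences. From day 12 to day 19, the higher lists were MHC class II (0.94), interferon response (0.83), atrial (0.72), macrophage (0.59), mesothelium (0.57), immediate-early (0.55), lymphocyte (0.49), hypertrophy markers (0.46), ER stress (0.25), cell cycle (0.16), ribosomal proteins (0.13) and matrix enzymes (0.13). The lower lists were ion channels (-0.30), mural (-0.28), calcium handling (-0.25), endothelial (-0.20), oxidative phosphorylation (-0.18), fatty acid use (-0.15) and basement membrane (-0.15). Of these 19 lists 0 passed with an estimated correlation (adjusted p = 0.381 to 0.544).

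From day 19 to post-partum day 1.5, the higher lists were collagens (0.48), cell cycle (0.36), circadian clock (0.33), proteoglycans (0.28), ion channels (0.24), basement membrane (0.23), calcium handling (0.19) and oxidative phosphorylation (0.17). The lower lists were MHC class II (-1.44), atrial (-1.26), interferon response (-1.04), mesothelium (-0.63), macrophage (-0.43), immediate-early (-0.42), ER stress (-0.37) and fatty acid use (-0.20). Of these 16 lists 0 passed with an estimated correlation (adjusted p = 0.572 to 0.574). Members of the circadian clock list moved both ways. Dbp went from 8.35 and 7.67 at day 19 to 9.24 and 9.36 post-partum, and Ciart from 5.85 and 6.08 to 7.12 and 7.31. Arntl went down from 7.91 and 7.36 to 6.36 and 6.67, and Npas2 from 7.46 and 7.47 to 6.64 and 6.49.

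Day 19 replicate 2 stood apart from the other 7 arrays, and the immune lists called at day 19 rest on it; the reproductive state was not tested as an explanation, since the pattern is on 1 array. A loss of contrast over the whole array would move lists of matched level alike. The macrophage list, 1.08 log2 higher than on replicate 1 by its median, lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.19. So did interferon response (2.34), MHC class II (2.68) and cell cycle (0.34) among theirs. Oxidative phosphorylation (-0.32) lay at percentile 0, collagens (-0.52) at 0.03 and hypertrophy markers (-0.20) at 27.3. The lists did not move alike, but the immune lists had already been seen to be high on this array. The random lists also drew genes independently, unlike a list whose members vary together. A loss of contrast beside other differences is therefore not excluded. More macrophages in that piece stay open: 15 of 18 markers were higher there than on each other array (C1qb at 11.73 against at most 10.60 and Lyz2 at 11.57 against at most 10.68), with Cd163, F13a1 and Cd14 the exceptions, but this count restates the high list and adds no support. Of 9 lymphocyte genes 6 were higher there than on each other array, among them Nkg7 (9.47 against at most 5.97) and Cd3g (7.17 against at most 4.66). The B cell genes Cd79a (4.92 against at most 5.72) and Cd79b (5.61 against at most 6.13) and Thy1 (7.17 against at most 7.69) were not. The 2 neutrophil genes tested were higher there, Csf3r at 6.88 against at most 5.67 and Cxcr2 at 6.39 against at most 6.07. Blood in the piece stays open, since the differences of 5 red cell markers to the highest other array ran from -0.50 to -0.021, while haemoglobin genes were not among the genes measured here.

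Atrial markers were high on 3 arrays: Myl7 was 8.24 on diestrus replicate 3, 10.04 on day 12 replicate 3 and 11.76 on day 19 replicate 1, against 4.56 to 5.12 on the other 5. A rise with the stage at day 19 would put both day 19 arrays above diestrus, but the mean of Sln, Myl7 and Bmp10 on the lower day 19 array was -1.71 relative to the higher diestrus array. This followed from the pattern, since diestrus replicate 3 is 1 of the 3 high arrays, so it cannot judge an effect of the stage. Of Sln, Myl7 and Bmp10, only Bmp10 was higher on both day 19 arrays (8.06 and 5.12) than in diestrus (4.35 and 4.86). Among the other list members Gja5 was higher on both day 19 arrays (5.95 and 5.83 against 5.46 and 5.67). Kcnj3 was lower on both (9.11 and 8.82 against 9.43 and 9.41). Sln and Myl7 were 4.52 and 4.56 on day 19 replicate 2, against 4.51 and 5.12 on diestrus replicate 2. Atrial tissue in some of the pieces is a candidate explanation, found and tested on the same arrays: Dkk3, Mybphl, Kcnj3, Stard10 and Gja5 were higher on the array with the higher Myl7 in 12 of 15 combinations of marker and pair, the lowest number set as enough, with 5 of 5 at day 19, 4 of 5 at day 12 and 3 of 5 in diestrus. Over all 9 list members beside Myl7 it was 22 of 27, but Nppa was higher in 1 of 3 pairs, with 11.92 and 11.03 in diestrus and 11.23 and 11.13 at day 12 on replicates 2 and 3. Mesothelium markers were also highest on that day 19 array (0.97), while Myh7 was higher on both day 19 arrays, of which replicate 2 had low Myl7.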

How the results depend on the processing

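Tests that left out day 19 replicate 2 and post-partum replicate 2 together, or used atrial markers as a covariate, were chosen after seeing the data, and genes named here from counts of 5 or fewer were named after their values were seen. No setting that kept all arrays and tested without a block called more than 1 gene at adjusted p under 0.05: array weights called 1 at day 12 (Snord99), and a trended robust variance, the stricter filter and repeated quantile normalization each called 1 from day 19 to post-partum (Scd4), and an adjusted p under 0.1 called 1 there. With no filter, median centring, fits of the compared groups only and every probe set on its own the count stayed 0. At an unadjusted p under 0.05 with 1.5-fold, 99, 394, 245, 340 and 432 genes passed in the 5 comparisons, and the overlaps were 35, 11 and 42. Leaving out each array in turn gave 0 to 1 genes at day 12, 0 to 1233 at day 19, 0 to 3 post-partum, 0 to 1312 from day 12 to day 19, 0 to 872 from day 19 to post-partum, 0 to 663 in the F test and 0 to 1 in each overlap. Without diestrus replicate 2 the 1 gene was Erv3 in all 3 comparisons. Leaving out the 2 arrays together gave 2 from day 12 to day 19. The large counts came without day 19 replicate 1, where the pair that sets the widest spread is gone and replicate 2 alone stands for its group.

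Day 12 and diestrus share replicate numbers 2 and 3; their deviations correlate at 0.22, but 2 pairs are too few to show pairing. With the replicate block, which leaves 1 residual degree of freedom, 18, 2465, 599, 2635 and 2442 genes passed in the 5 comparisons and 2633 in the F test, and 1 list post-partum. Replicate number 1 occurs on 1 day 19 array alone and number 4 on 1 post-partum array alone, so the block fits these 2 arrays exactly and day 19 and post-partum rest on their replicate 2, which at day 19 is the array that stands apart, with the spread taken from diestrus and day 12; the cause of the 18 at day 12 was not tested. Under the block Col1a1 and Col3a1 at day 19 gave -0.17 and -0.19 and Nppa post-partum -0.52, and the means of fatty acid use at day 19 and of atrial markers from day 12 to day 19 were -0.031 and -0.046.

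No list, 0 in each comparison, passed with an estimated correlation or with fry. Of the 62 calls of a list in a comparison, 62 were kept with a variance trend, 59 with median centring, 58 without the filter, 51 with the atrial covariate, 43 with the block and 36 with the 2 arrays left out. Leaving out single arrays gave 3 to 10 lists at day 12, 1 to 7 post-partum, 12 to 20 from day 12 to day 19 and 8 to 20 from day 19 to post-partum; leaving out the 2 arrays together gave 9 post-partum. Then MHC class II at day 19 was -0.29 and oxidative phosphorylation 0.0055, from day 12 to day 19 cell cycle was -0.0076, interferon response -0.36, lymphocyte -0.11 and MHC class II -0.24, and from day 19 to post-partum calcium handling was -0.0070, proteoglycans -0.043, oxidative phosphorylation -0.0042, interferon response 0.33 and macrophage 0.25. Of these the MHC class II list at day 19 and from day 12, the interferon list from day 12 and to post-partum and the macrophage list to post-partum passed in the opposite direction (adjusted p = 0.00503, 0.0298, 3.69e-09, 7.68e-06 and 3.81e-05); Ciita, H2-DMa, H2-Eb1 and H2-Ab1 at day 19 gave -0.017, -0.31, -0.31 and -0.42. With the atrial covariate Col1a1 at day 19 gave -0.11. Means that changed sign when a single array was left out ranged over -0.20 to 0.012 for ribosomal proteins at day 12; at day 19, over -0.32 to 0.0055 for oxidative phosphorylation, -0.10 to 0.97 for mesothelium, -0.29 to 2.07 for MHC class II and -0.38 to 2.10 for atrial markers; from day 12 to day 19, over -0.0076 to 0.32 for cell cycle, -0.36 to 2.03 for interferon, -0.11 to 1.09 for lymphocyte, -0.24 to 2.11 for MHC class II and -0.51 to 1.96 for atrial markers; and from day 19 to post-partum, over -2.24 to 0.16 for interferon and -0.93 to 0.067 for macrophage. With only day 19 replicate 2 left out, MHC class II at day 19 and from day 12 and the interferon response from day 12 passed as lower (adjusted p = 0.00515, 0.0365 and 8.13e-08). Single genes ranged at day 12 over -0.74 to 0.15 for Nppa, -0.37 to 0.56 for Nppb, -0.37 to 0.27 for Myh7 and -0.20 to 0.012 for Col1a1; at day 19 over -0.017 to 2.13 for Ciita, -0.31 to 2.92 for H2-DMa, -0.31 to 2.48 for H2-Eb1, -0.42 to 2.59 for H2-Ab1, -0.21 to 2.18 for Upk1b, -0.22 to 0.29 for Col1a1 and -0.15 to 0.40 for Col3a1; and post-partum over -0.31 to 0.58 for Nppa. Where a mean or a gene turned, the cause was the loss of the array named in the setting or was not tested. All 189 values of named genes kept their direction and stayed above the threshold of adjusted p with array weights, a trended robust variance, no filter, median centring, repeated quantile normalization and fits of the compared groups only, as did the 143 with a value under the stricter filter; other probe sets that lacked a gene's change are given beside it. RMA values carry no measure of background, and genes near the filter of 5.19 can change less than their RNA.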

Other observations

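All tests in this part were chosen after the result was seen, the classes of other small RNAs and their limits were revised after a first result, and the gene classes in it were not among the lists fixed beforehand. The 51 small nucleolar RNA genes tested, which guide the modification of ribosomal and spliceosomal RNA, were lower at day 12 than in diestrus in 44 cases, with a median of -0.66 log2 or 1.58-fold (camera with the preset correlation, adjusted p = 5.15e-37 over 3 classes in 5 comparisons; adjusted p = 0.146 with an estimated correlation). Among them Snord99 gave -1.91, Snord49b -1.54, Snord35a -1.45, Snord82 -1.33 and Snord71 -1.25. The median of the class was -0.47 at day 19 and -0.081 post-partum. Its mean level on replicates 2 and 3 was 7.26 and 7.63 in diestrus and 6.58 and 6.94 at day 12. The arrays of 1 group thus differed as well. The mean was 7.05 and 6.97 on the day 19 arrays and 7.56 and 7.28 post-partum. None of these genes passed over all genes tested.

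The RNA levels of the host genes that contain these RNAs differed less at day 12. Hosts were assigned by position without regard to strand. Of 31 hosts tested 23 were lower, and as a class they passed with the preset correlation (camera, adjusted p = 0.0168). With an estimated correlation they did not pass (camera, adjusted p = 0.415). Their median was -0.060, with a 95% bootstrap interval of -0.13 to -0.025. That interval resampled genes and holds no spread between samples. A lower output of the hosts stays open, since the arrays measure the level of host RNA and not its production. A loss of all small RNAs in preparation or labelling, microRNA precursors included, stays open: the median of 130 other small RNA genes was 0.087, but 119 of them were microRNA precursors with a median level of 6.12 against 6.81 for the small nucleolar RNAs, and genes near the filter of 5.19 can change less than their RNA. Among the 11 other stable small RNAs, at a median level of 8.93, the median was -0.45 with an interval of -1.42 to -0.0030, with Rny1 at -1.60, Rny3 at -1.58 and Vaultrc5 at -1.42 but Rn7sk at 0.0093 and Rnu12 at -0.048. A difference in recovery or labelling of small RNAs between samples may produce the pattern, and it cannot be told apart from an effect of pregnancy with 2 arrays per group.

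Clock genes differed between the 2 diestrus arrays: Dbp was 7.82 on replicate 2 and 9.71 on replicate 3, Ciart 5.57 and 7.82, Arntl 8.39 and 5.82, and Npas2 8.16 and 6.20. At day 19 Dbp was 8.35 and 7.67 and Npas2 7.46 and 7.47. The day 12 and post-partum arrays ranged from 9.10 to 9.36 for Dbp and from 6.49 to 6.64 for Npas2. Arntl was 7.38 and 7.09 at day 12, 7.91 and 7.36 at day 19 and 6.36 and 6.67 post-partum.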
